A study of Homo sapiens with 6 samples.

How the data were processed

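RNA was measured in 6 libraries of PC9, a human lung adenocarcinoma cell line that carries an activating EGFR mutation and is sensitive to the EGFR inhibitor gefitinib. Per the labels, the cells overexpressed FOXM1, a transcription factor of the mitotic programme, as 1 of 2 alleles of the variant rs3742076. The A allele was expressed in 3 libraries and the G allele in 3 libraries, and the cells of all 6 libraries received 100 nM gefitinib for 24 h. Per the labels' protocols, poly(A) RNA was selected with oligo(dT) beads, the second cDNA strand was marked with dUTP and removed, and the libraries were sequenced as read pairs on a NovaSeq instrument.

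Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.0.4 and StringTie 1.3.4d. The same notes name a mouse genome build, which the files contradict: the features carry human Ensembl identifiers, and of 206348 transcripts found by identifier in GENCODE release 29, 94.6% had the same GRCh38 position and strand. Positions are therefore given on GRCh38, as the deposited transcript table gives them. The strand setting, annotation release and test of the authors are not given in the sources used here.

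Both deposited tables hold FPKM, fragments per kilobase of transcript, scaled by the mapped fragments of the library, for 58825 genes and for 208460 transcripts. The authors' tables also hold a fold ratio, its log2 value, a p-value and a q-value, per the file headers. The deposited log2 fold change equalled the log2 ratio of the G mean over the A mean for all 58825 genes within 1e-06. All 216 genes that the authors' deposited table marks as significant had a deposited p under 0.05 and an absolute log2 change of at least 1, with no condition on the q-value. A value of 0.0001 stands for no estimate, and 28089 genes had it in every library. For the 16694 genes above 0.1 FPKM in all libraries, the gene value was a fixed multiple of the length-weighted sum of its transcripts, within 1%. Reads that StringTie shifts between overlapping genes therefore move these values, while shifts between isoforms of a gene move only its transcript values.

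The step that 1 read pair makes in the FPKM of single-exon genes longer than 400 bases gave 19765200 to 23289020 read-pair equivalents per library. That step was sought only within a preset window, which bounds these depths in advance, so they are estimates. Of the low values of those genes, 25.4% to 28.1% were whole multiples of that step within 0.02 read pairs, so whole reads were not recovered and no count model was used.

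Values were taken as log2(FPKM + 1), and fold changes are G minus A on that scale, which understates the change of low genes. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 12787 in all. The test was limma 3.58.1 with an intensity trend (limma-trend, R 4.3.3), with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The same fit was run on 29990 transcripts. The 26 gene lists were written before the data were examined and tested with camera of limma at a preset inter-gene correlation of 0.01. Camera compares the genes of a list with all other tested genes. FOXM1 was also tested with an exact two-sided permutation test.

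Genes were named by a rule also fixed in advance. It takes FOXM1, up to 10 called genes per direction with non-overlapping groups (filled up by the smallest unadjusted p, as values only), the members of each list with the smallest p, the most expressed called genes and 12 genes of Wnt, EGFR and cell cycle biology. Tables were read with Python 3.11.15 and pandas 2.3.3.

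The fit was tested on simulated data for the comparison of G with A over 12787 genes. It recovered 56% of genes changed 1.5-fold, 80% of those changed 2-fold and 96.4% of those changed 4-fold, with 37 false calls among 62935 unchanged genes over 5 runs. These changes were set on the log2(FPKM + 1) scale, and in more genes than were called in the real data. In data drawn separately in the same runs, the Wnt target list shifted by 0.2 on the log2 scale was called in 5 of 5. The other lists were called in 0 of 125 tests. Some of them were partly shifted, since 12 of the 28 tested Wnt targets are also in another list. The simulated noise was independent between genes, so this cannot show how often lists of correlated genes are called falsely. In the real data the estimated correlation was 0.44 for mitochondrially encoded genes and 0.34 for ribosomal protein genes.

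The alternatives changed the pseudocount, the filter, the scaling, the variance model, the library weights, the replicate block and the set of libraries. The planned enrichment of terms needed 20 called genes in a direction and was not run. No library without FOXM1 overexpression and none without gefitinib was analysed here, so neither effect was measured. The labels do not say whether the replicates were separate cultures, and p-values then measure only the spread between these libraries, which may be technical.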

Results

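Poly(A) RNA of gefitinib-treated PC9 cells was compared between 3 libraries expressing the A allele of FOXM1 rs3742076 and 3 libraries expressing the G allele. The libraries were estimated to hold 19765200 to 23289020 read-pair equivalents. In each, between 12451 and 12858 genes reached 1 FPKM. The log2 values correlated at 0.974 to 0.979 within groups and at 0.970 to 0.976 between groups across genes, and no 2 columns were identical. The series asks whether the variant changes the response to gefitinib through Wnt/β-catenin signalling, and its design names G against A as the comparison.

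FOXM1 mRNA (ENSG00000111206, chromosome 12, 2857681 to 2877155) did not separate the groups. It was 15.3 FPKM ± 8.81 (SD, n = 3) in A libraries and 14.3 FPKM ± 0.34 (SD, n = 3) in G libraries. The log2 change was 0.03 with a 95% interval of -0.77 to 0.83, and the exact two-sided permutation test gave p = 1, where 3 against 3 libraries cannot go below 0.1. The spread came from A replicate 1, at 25.5 FPKM, against 10.5 and 10.1 FPKM in the other A libraries and 13.96 to 14.6 FPKM in the G libraries. Without A replicate 1 the log2 change was 0.44 ± 0.057 (SE), with a limma adjusted p of 0.087. A replicate 1 also lay between the groups on the first principal component, at 0.44, where the other A libraries lay at -20.9 and -15.2 and the G libraries at 8.67 to 14.8. That component held 28.3% of the variance.

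Few single genes passed the test. HK2, the hexokinase that starts glycolysis, rose from 25.7 FPKM ± 0.74 to 38.3 FPKM ± 0.67 (SD, n = 3). SPSB1, an adaptor of ubiquitin ligases, rose from 4.80 ± 0.72 to 10.0 ± 0.23 FPKM, C6orf89 from 4.78 ± 0.59 to 9.50 ± 0.066 FPKM and the zinc finger gene ZNF224 from 1.96 ± 0.30 to 4.49 ± 0.059 FPKM. In the other direction, LASP1, an actin-binding scaffold, fell from 87.0 ± 2.56 to 27.1 ± 4.11 FPKM, the antiapoptotic BCL2 relative BCL2L2 from 9.28 ± 2.04 to 1.02 ± 0.15 FPKM, and MAFF, a small basic leucine zipper factor, from 5.90 ± 0.36 to 1.66 ± 0.27 FPKM. In total 14 of 12787 genes were called by limma-trend, 4 higher and 10 lower in G. Of these, 4, all lower, changed at least 2-fold on the log2(FPKM + 1) scale, a count that was 7 with a pseudocount of 0.1 or 0.01. The highest 2-fold count among the other splits of the 6 libraries, 3 against 3, was 8.

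**Figure D1:**
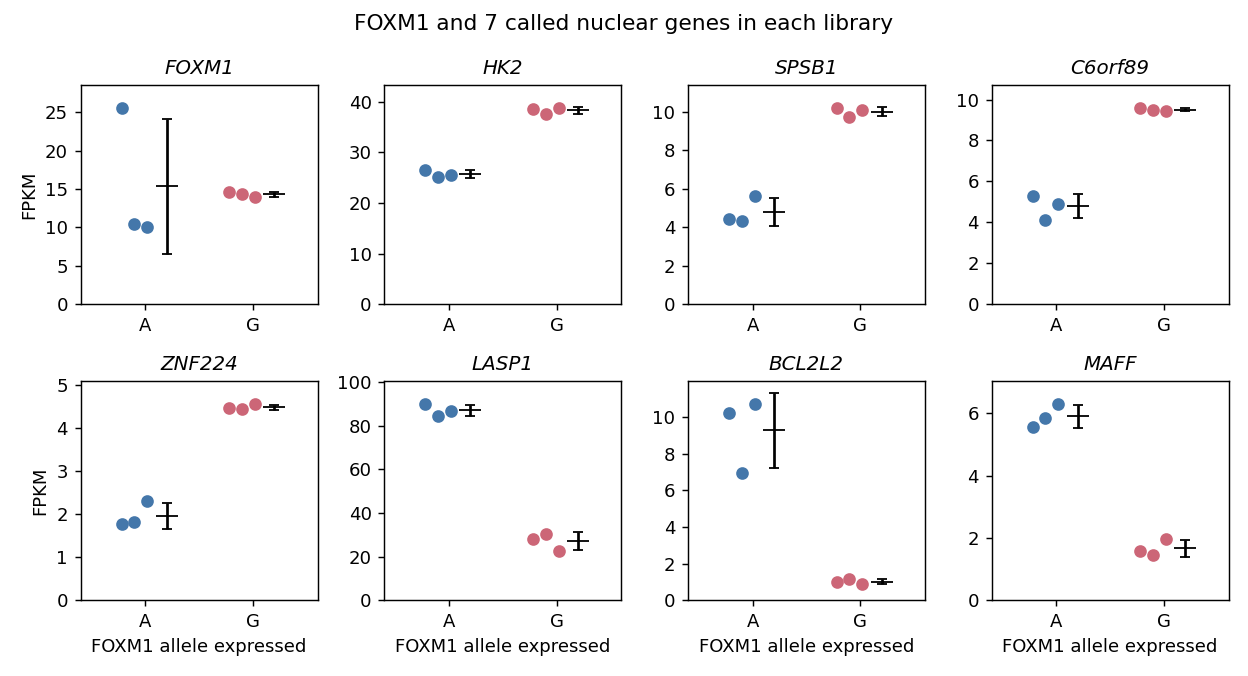
FPKM of FOXM1 and of 7 called nuclear genes in each library, with the 3 A libraries in blue, the 3 G libraries in red and mean and SD as horizontal marks with bars. FOXM1 reaches 25.5 FPKM in A replicate 1 and the groups overlap, while in the other panels all 3 libraries of one group lie above those of the other.

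The log2 changes were 0.55 for HK2 (limma adjusted p = 0.0257), 0.93 for SPSB1, 0.89 for ZNF224 and 0.87 for C6orf89 (each adjusted p = 0.046). They were -2.33 for BCL2L2, -1.66 for LASP1 and -1.38 for MAFF (each adjusted p = 0.0144). Under the alternative settings HK2 was called in 11 of 19, C6orf89 in 8 of 19, SPSB1 in 7 of 19 and ZNF224 in 6 of 18. LASP1 was called in 15 of 19, BCL2L2 in 13 of 19 and MAFF in 12 of 18. BCL2L2 lies on chromosome 14 at 23298790 to 23311759 and LASP1 on chromosome 17 at 38869859 to 38921770. HK2 lies on chromosome 2 at 74833981 to 74893359 and MAFF on chromosome 22 at 38200767 to 38216507. The other nuclear calls were TGFB2-OT1 (log2 change -2.06), a short RNA inside the TGFB2 gene, and VPS33B (-0.93), a vesicle-sorting gene. Both overlap another gene on the same strand, and the summed read pairs of each locus did not separate the groups, so these 2 calls are uncertain. With whole chains of overlapping genes summed, BCL2L2 was not called either (log2 change -0.43, adjusted p = 0.15), in a sum that took in PABPN1, named after its values were seen, at 21.1 ± 1.24 and 21.7 ± 1.57 FPKM. The remaining 5 calls were 4 mitochondrial mRNAs and MTATP6P1, a nuclear copy of mitochondrial sequence, whose call is uncertain because reads shared with the mitochondrial genome were not measured.

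The number of calls depended on single libraries. It was 5 without A replicate 2, 5 without A replicate 3 and 20 without A replicate 1. Without G replicates 1, 2 and 3 it was 10, 6 and 5. Of the 14 calls, the fits without A replicates 1, 2 and 3 kept 8, 2 and 2. Those without G replicates 1, 2 and 3 kept 4, 3 and 3. Which genes were called thus changed too, though all 14 kept their sign in these fits. At an unadjusted p under 0.05, 2212 genes passed (17.3%), and in 24.9% of the tested genes the groups did not overlap, where chance gives 10%. The split of higher and lower calls also moved with scaling, from 4 and 10 to 7 and 8 with equal sums per library, where the median log2 change of all genes was 0.11 instead of 0.02, and to 1 and 7 with median-ratio factors. The authors' deposited table marks 216 genes, 145 higher and 71 lower in G. Of those, 63% were below 1 FPKM in at least 4 libraries. The same table has 54 genes with q under 0.05, which include 13 of the 14 calls.

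Genes of hypoxia and glycolysis rose together in the G libraries. Of 37 tested members 33 had a positive log2 change, with a median of 0.20. Camera called the list (adjusted p = 2.0e-10), and it was the list whose call held with an estimated correlation (adjusted p = 0.038). Over all genes 1 member was called higher, and 18 were higher when adjusted over the list alone. Besides HK2 these included the glucose transporter SLC2A3, at 38.7 ± 0.82 and 52.2 ± 1.71 FPKM in A and G, the oxidoreductase ERO1A, at 30.5 ± 0.21 and 40.6 ± 1.34 FPKM, and the transcriptional repressor BHLHE40, at 74.1 ± 2.43 and 90.7 ± 2.24 FPKM. None of these 3 passed over all genes (adjusted p = 0.061, 0.069 and 0.15). HILPDA, a lipid droplet gene outside the list, was at 22.2 ± 2.09 and 33.0 ± 0.44 FPKM (adjusted p = 0.11).

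The list of FOXM1 and G2/M targets rose as a group. Of 66 members 52 had a positive log2 change, with a median of 0.16 (camera adjusted p = 4.8e-06). With an estimated correlation the adjusted p was 0.17. Over all genes 0 members were called by limma, and 10 were higher when adjusted over the list alone. These included DEPDC1, at 4.36 ± 0.37 FPKM in A and 7.71 ± 0.85 FPKM in G, the topoisomerase TOP2A, at 33.2 ± 1.42 and 42.9 ± 2.40 FPKM, the kinetochore gene CENPF, at 15.5 ± 0.97 and 20.1 ± 0.76 FPKM, and the spindle motor KIF11, at 14.4 ± 0.89 and 18.6 ± 0.73 FPKM. CCNB1 (log2 change -0.08, adjusted p = 0.53) and AURKA (0.21, adjusted p = 0.72) were not called. The G1/S and replication list was also called higher, with 44 of 60 members positive and a median of 0.14 (camera adjusted p = 0.0044), but 0 members were higher when adjusted over the list alone. Its adjusted p was 0.30 with an estimated correlation. With trends over gene length and GC content removed, both lists were still called, with medians of 0.10 and 0.08.

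Wnt/β-catenin target genes, the readout named in the series title, were not called. Of the 57 genes of this list only 28 passed the filter of 1 FPKM and were tested, so the result covers those 28 alone. Among them 20 had a positive log2 change, the median was 0.04 and camera gave an adjusted p of 0.38. Adjusted over the list alone, VEGFA was higher, at 18.4 ± 0.73 and 22.0 ± 0.55 FPKM in A and G. CCND1 was lower, at 9.73 ± 0.21 and 7.65 ± 0.28 FPKM. VEGFA is also a member of the hypoxia and glycolysis list, and CCND1 of the EGFR/MAPK output list. Over all genes neither passed (adjusted p = 0.16 and 0.15). CTNNB1, which encodes β-catenin, was at 15.7 ± 0.64 and 16.5 ± 0.24 FPKM (log2 change 0.07, adjusted p = 0.54), and MYC was at 3.51 ± 1.39 and 4.47 ± 0.43 FPKM (adjusted p = 0.51). The targets AXIN2 and LEF1 were below 1 FPKM and were not tested, with means of 0.21 and 0.19 FPKM for AXIN2 and of 0.52 and 0.52 FPKM for LEF1. Of 95 Wnt pathway components 59 were tested, and 30 of these had a positive log2 change (camera adjusted p = 0.90). The test fry asks whether the genes of a list move one way, without comparing them with other genes. It called the Wnt targets higher (fry adjusted p = 0.028), but was run only on the deposited values. The list's median was 0.005 with median-ratio factors and with quantile normalization, and 0.13 with equal sums per library.

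**Figure D2:**
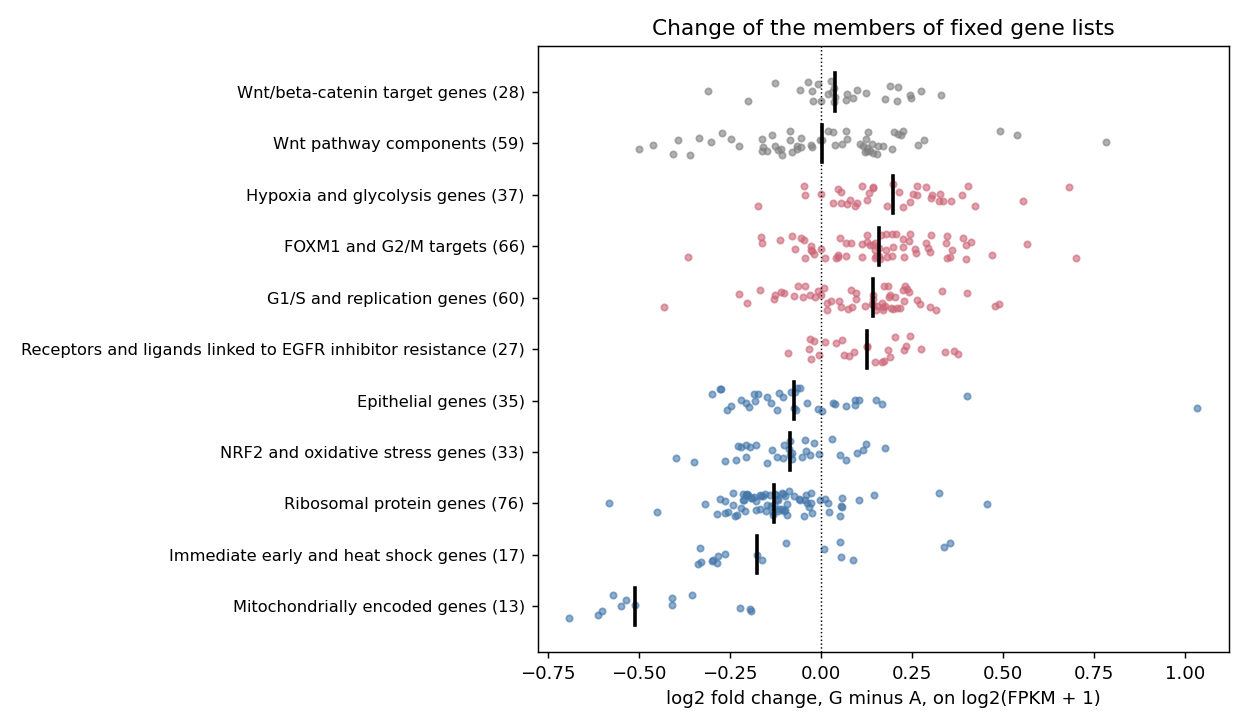
Log2 fold change, G minus A, of each tested member of the called gene lists with at least 5 tested members (red for a positive median, blue for a negative one) and of both Wnt lists (grey), with medians as black bars and tested members counted in brackets. On the deposited scale the medians run from -0.51 for mitochondrially encoded genes to 0.20 for hypoxia and glycolysis genes, and both Wnt lists lie near 0, while with equal sums per library, where all genes have a median of 0.11, the NRF2 and epithelial medians are 0.02 and 0.03.

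The mRNAs of the mitochondrial genome, which encode parts of the respiratory chain, were lower in the G libraries. All 13 had a negative log2 change, with a median of -0.51 (camera adjusted p = 1.8e-17), with 4 called lower over all genes and 12 lower when adjusted over the list alone. The list's call was lost with an estimated correlation (adjusted p = 0.13). MT-CO3 fell from 3733 ± 80.1 to 2312 ± 154 FPKM (limma adjusted p = 0.0241), MT-ND1 from 4754 ± 246 to 3246 ± 158 FPKM (adjusted p = 0.046) and MT-CYB from 1844 ± 66.2 to 1215 ± 46.3 FPKM (adjusted p = 0.0241). Mitochondrial genes made up 22.1% ± 0.07 (SD, n = 3) of the summed FPKM in A libraries and 18.7% ± 0.98 in G libraries. The median kept its sign under each scaling tried and was -0.16 with quantile normalization.

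**Figure D3:**
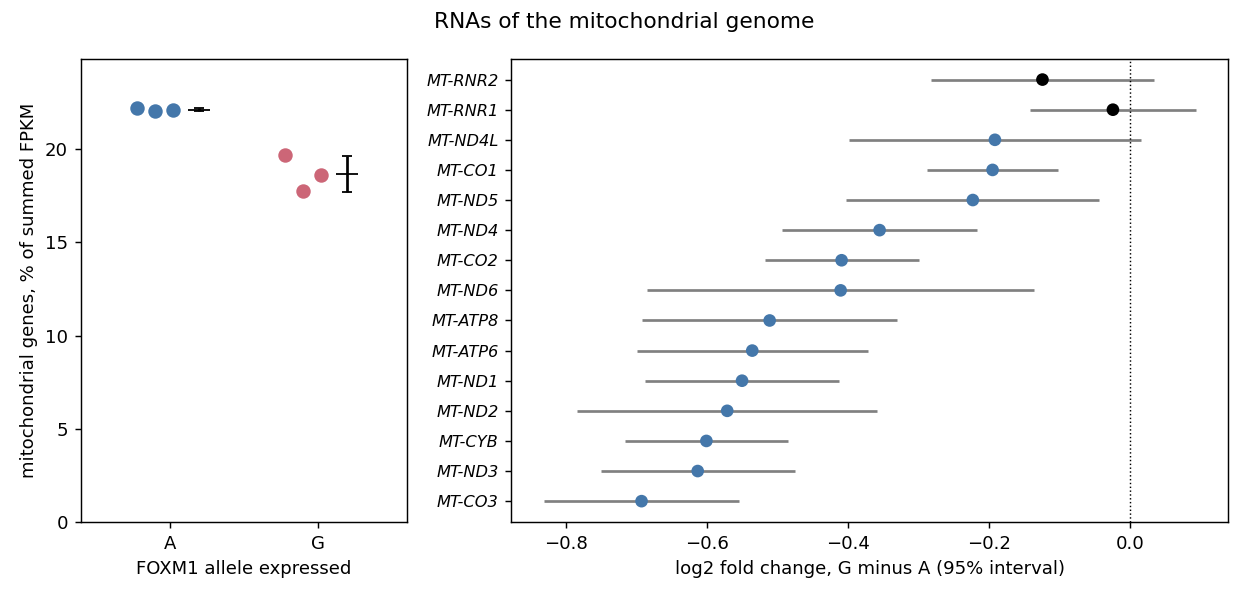
Left, the share of summed FPKM from mitochondrial genes in each library, with mean and SD, and right, log2 fold changes with 95% intervals of the 13 mitochondrial mRNAs (blue) and of the rRNAs MT-RNR1 and MT-RNR2 (black). The share was 22.1% in A and 18.7% in G, and the rRNA changes of -0.02 and -0.12 lie nearer 0 than those of the mRNAs.

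Ribosomal protein genes were called lower than other genes, with 65 of 76 negative and a median of -0.13 (camera adjusted p = 4.8e-11). When adjusted over the list alone, 0 members were called. The adjusted p was 0.30 with an estimated correlation, 0.10 with fry and 0.38 with quantile normalization, where the median was -0.02. With equal sums per library the median itself was also -0.02, but relative to all genes it was -0.13, against -0.15 on the deposited scale. With trends over gene length and GC content removed the median was -0.06 (adjusted p = 0.00068). Antioxidant genes of the NRF2 list were called lower than other genes (26 of 33 negative, median -0.09, adjusted p = 0.00035), but the call was lost with an estimated correlation (adjusted p = 0.13), with equal sums per library (adjusted p = 0.065) and with quantile normalization (adjusted p = 0.94). With equal sums the median itself was 0.02, but relative to all genes it was -0.09, against -0.11 on the deposited scale. The member with the smallest p was TALDO1 of the pentose phosphate pathway, lower when adjusted over the list alone, at 159.2 ± 2.69 and 132.4 ± 0.50 FPKM. Immediate early and heat shock genes, a sign of stress at harvest, were also called lower than other genes (11 of 17 negative, adjusted p = 0.0013). That call was lost with an estimated correlation (adjusted p = 0.13), and 3 members were lower when adjusted over the list alone. HSPA1A, a heat shock chaperone, was at 160.1 ± 1.501 and 127.1 ± 5.11 FPKM, lower when adjusted over the list alone. Over all genes neither TALDO1 nor HSPA1A passed (adjusted p = 0.13 and 0.11).

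Receptors and ligands linked to EGFR inhibitor resistance were higher as a group, with 21 of 27 positive (camera adjusted p = 0.0028), and 0 were called when adjusted over the list alone. The list's call was lost with an estimated correlation (adjusted p = 0.26) and after removal of trends over gene length and GC content (adjusted p = 0.43). EGFR was at 67.1 ± 5.95 and 84.9 ± 1.32 FPKM (adjusted p = 0.16) and MET, a bypass receptor, at 5.75 ± 0.47 and 7.15 ± 0.43 FPKM (adjusted p = 0.20). AXL was not called (4.07 ± 0.19 and 4.84 ± 0.33 FPKM, adjusted p = 0.24).

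Epithelial genes were called lower than other genes (24 of 35 negative, median -0.08, adjusted p = 0.0044), a call kept in 18 of 22 settings. Among the settings that lost it were an estimated correlation (adjusted p = 0.29), quantile normalization (adjusted p = 0.34) and fry (adjusted p = 0.077). With equal sums per library the median itself was 0.03, but relative to all genes it was -0.08, against -0.10 on the deposited scale. KRT7 was at 445.8 ± 20.96 and 368.5 ± 24.1 FPKM (adjusted p = 0.18 over all genes), while the desmosome gene DSP was higher when adjusted over the list alone, at 94.7 ± 8.64 and 125.0 ± 3.48 FPKM (adjusted p = 0.15 over all genes). CDH1 was at 45.9 ± 11.1 and 50.9 ± 11.8 FPKM (adjusted p = 0.74), and VIM was below 1 FPKM. Lung lineage genes (3 of 27 tested, adjusted p = 0.0098) and endothelial markers (2 of 13 tested, adjusted p = 0.049) were also called lower, the latter in 9 of 21 settings. With an estimated correlation the adjusted p of these 2 lists was 0.19 and 0.30.

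The other 13 lists were not called, though 1 BCL2 family member (BCL2L2) and 1 EGFR/MAPK output gene (MAFF) were called lower over all genes. Mesenchymal genes had an adjusted p of 0.092 and replication-dependent histone genes one of 0.091. The adjusted p was 0.12 for BCL2 family genes, 0.19 for interferon response, 0.36 for drug transporters, 0.46 for inflammatory genes, 0.60 for stemness genes, 0.82 for cholesterol synthesis and 0.92 for p53 targets. It was 0.38 for leukocyte markers, for TGF-β and YAP targets, for ATF4 and unfolded protein response genes and for EGFR/MAPK output genes. For EGFR/MAPK output genes the median was 0.01 and the mean -0.05, and for stemness genes and Wnt components both were above 0, while camera's direction was down in these 3 lists.

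At transcript level 44 of 29990 transcripts from 41 genes were called, 23 higher and 21 lower in G, and 42 changed at least 2-fold. The count was 0 with a pseudocount of 0.01, and the highest count among the other splits of the 6 libraries, 3 against 3, was also 44. For 5 of the 44 the gene was called as well, among them the main transcripts of BCL2L2 (ENST00000250405, 10.3 and 0.28 FPKM) and MAFF (ENST00000338483, 13.8 and 2.30 FPKM). The main transcript of LASP1 (ENST00000318008) was not called (149.3 ± 3.53 and 28.6 ± 18.3 FPKM, adjusted p = 0.43), and G replicate 1 had 82.1 FPKM of ENST00000443937, a LASP1 transcript at 8.31 and 14.2 FPKM in the other G libraries. For the other called transcripts the gene itself was not called. Transcript ENST00000475680 of UBE2E1, chosen as an example after its values were seen, was at 0.027 FPKM in A and 24.3 FPKM in G with a gene log2 change of 0.07. With transcript FPKM summed per gene without length weights, a measure that shifts between isoforms move, 2 of 14016 genes were called. With the deposited gene values it was 14. Of the FOXM1 transcripts the most abundant was ENST00000342628, at 11.2 ± 7.13 FPKM in A and 11.5 ± 0.13 FPKM in G (adjusted p = 0.91).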

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

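The added settings, namely mitochondrial genes left out, trends over length and GC content removed and overlapping genes summed, were chosen after seeing the data, and all others before the data were examined. The count of called genes moved from 14 to 1 without a filter on low values, 6 with quantile normalization, 8 with median-ratio factors, 4 without a variance trend, 6 with mitochondrial genes left out, and 5 to 20 when 1 library was left out. By the authors' deposited table it was 54 at q and 844 at p under 0.05. The causes were not tested. The 14 calls kept their sign in the 19 gene-level settings where they were tested, but with chains of overlapping genes summed VPS33B turned (log2 change 0.057). In that setting 13 loci were called, holding 11 of the 14 calls. The count at 2-fold was 4, and 7 with a pseudocount of 0.1 or 0.01, 1 without a filter, 2 at a mean of at least 5 FPKM and 5 to 12 with a library left out (12 without A replicate 1). The 44 called transcripts became 23 and 0 with the smaller pseudocounts, 7 without a filter and 5 at a mean of at least 5 FPKM. With a library left out they were 7 to 37 (37 and 27 without A replicates 1 and 2, 7 without A replicate 3, and 15, 16 and 17 without G replicates 1, 2 and 3). As unweighted sums of transcript FPKM per gene, 2 genes were called.

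The replicate numbers were not taken to pair the libraries, since the deviations of same-numbered libraries correlated at 0.073, 0.015 and 0.040 across genes, all under 0.1, which does not show that pairing is absent. With the replicate block 0 genes, 0 genes at 2-fold and 0 transcripts were called by limma, with 2148 genes at an unadjusted p under 0.05. Each A library correlated best with the G library of its own number, while G replicate 2 had nearly equal values with A replicate 2 and A replicate 3 (0.015 and 0.016).

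The 11 called lists became 7 with quantile normalization and 1 with an estimated correlation, and 9 to 12 with a library left out. FOXM1 and G2/M targets lost their call with an estimated correlation (adjusted p = 0.17) and kept it in 21 of 22 settings (range 7.2e-08 to 0.17). Wnt targets passed in 1 of 23 settings, with fry (adjusted p = 0.028, range 0.028 to 0.86). Hypoxia and glycolysis genes kept their call in 22 of 22 (range 3.2e-17 to 0.038). The log2 change of FOXM1 was -0.010 with median-ratio factors and -0.19 to 0.44 with a library left out, negative without A replicate 2 or A replicate 3.

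Among called lists, endothelial markers (2 genes) turned direction without a filter (adjusted p = 0.79), and the other lists that turned were not called. Without a filter leukocyte markers and p53 targets also turned (both 0.79). With length and GC trends removed, drug transporters (0.91), cholesterol synthesis (0.95) and p53 targets (0.87) turned. Quantile normalization turned ATF4 genes and p53 targets (both 0.99), and median-ratio factors turned p53 targets (0.97), whose adjusted p ran from 0.73 to 0.95 with a library left out. Inflammatory genes (0.95) and Wnt components (0.43) turned at a mean of at least 5 FPKM, TGF-β and YAP targets without shared genes (0.86), and Wnt components with fry (0.46) and with a library left out (0.70 to 0.99). CCNB1 turned with equal sums (log2 change 0.027). With a library left out CDH1 ran from -0.030 to 0.33 and AURKA from -0.13 to 0.38.

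Count models were not run because whole reads were not recovered, and term enrichment was not run because too few genes were called. At 2-fold the simulated fit recovered 80% of changed genes, so smaller changes can be missed. Each simulated run held more changed genes than were called here, which loosens the adjusted threshold, so 80% may be too high. In the real fit 43 genes had an absolute log2 change of at least 1 and 4 of them were called, so larger changes can be missed too.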

Other observations

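The tests of terms below and all tests of explanations, except the counts over other splits of the libraries, were chosen after the results were seen. Among terms that the deposited table pairs with genes, camera called 29 of 2863 GO terms higher and 73 lower in G, and 3 of 297 KEGG pathways higher and 13 lower. Genes of oxidative phosphorylation, mostly encoded in the nucleus, were called lower, with 19 of 117 positive and a median log2 change of -0.14 (adjusted p = 3.1e-12, and 0.79 with an estimated correlation). Proteasome genes were called lower as well, with 8 of 42 positive (adjusted p = 0.00043, and 0.79 with an estimated correlation). Genes of microtubule-based movement, which include mitotic kinesins, were called higher, with 38 of 43 positive and a median of 0.17 (adjusted p = 4.2e-05, and 0.86 with an estimated correlation). Genes of ECM-receptor interaction were called higher, with 34 of 41 positive (adjusted p = 0.0082, and 0.79 with an estimated correlation). With an estimated correlation camera called 0 of these terms. Trends over gene length and GC content were not removed for terms, so their part in these calls was not tested.

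The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 14 genes and the highest other split 10, so 1 of the 10 splits gave as many. For genes changed at least 2-fold the real count was 4 and the highest other 8, with 7 splits as large. For transcripts both were 44, with 3 splits as large, and for lists they were 11 and 3, with 1 split as large.

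The mitochondrial mRNAs were lower in the G libraries, with a median log2 change of -0.51. A single factor per library does not account for this, since the value closest to 0 over 3 such scalings was -0.40, a test added after the one over all scalings. Over all 4 scalings the value closest to 0 was -0.16, from quantile normalization, so part of the difference may come from scaling, although that method ties genes at the top of the expression range, where these mRNAs lie. A loss of every mitochondrial RNA is argued against by MT-RNR1, at 1177 ± 28.1 and 1158 ± 55.0 FPKM with a log2 change of -0.024, whose 95% interval of -0.14 to 0.09 lies above -0.51. The allele and an uneven capture of mitochondrial mRNAs by poly(A) selection stay open and were not tested.

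Reads moved between overlapping genes are a candidate explanation for the calls of TGFB2-OT1 and VPS33B, because the summed read pairs of each locus overlapped between groups, with a largest absolute log2 change of 0.10. The locus of TGFB2-OT1 and TGFB2 held 316.2 and 321.0 read-pair equivalents in A and G, and that of VPS33B and AC068831 held 911.3 and 978.5. For LASP1, BCL2L2, MAFF, HK2, C6orf89, ZNF224 and SPSB1 the locus sums still separated the groups, with a smallest absolute log2 change of 0.59. For all of them but BCL2L2, however, no gene that overlaps directly on the same strand held appreciable reads. Their sums were thus the genes' own values, and the separation followed from their being called. These sums show only that no such neighbour took up reads. For BCL2L2, summed with BCL2L2-PABPN1, the log2 change was -2.97. Over the whole chain of overlapping genes BCL2L2 was not called (log2 change -0.43, adjusted p = 0.15). For these 7 genes the allele, and differences between the libraries' cells that have nothing to do with it, stay open as untested.

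FOXM1 in A replicate 1 was 2.49 times the mean of the other A libraries. On a wrong label the first test was undecided, since in 10 of the 20 genes called without A replicate 1 that library lay nearer the G mean. A second test, added after that result, argues against A replicate 1 being a G library. In 13 of the 20 genes it lay outside the G range, towards A, by more than 3 SD of the G libraries. That SD comes from 3 libraries and is imprecise. The 20 genes were also called with these same G libraries, which favours a small SD, so the count of 13 may be too high. Another test, added later, argues against a mixture of A and G cells with the FOXM1 levels of the other libraries, since FOXM1 in A replicate 1 was 1.74 times the highest of the other 5 libraries. A higher level of the transgene in the cells of that library may account for it and was not tested.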
